A study of Mus musculus with 18 samples.

How the data were processed

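The values analysed are the deposited gene counts of 18 libraries of mouse quadriceps, 3 for each of 3 genotypes at 2 and 17 months. Groups, ages and replicate numbers were taken from the labels of the samples. The libraries were made with ScriptSeq v2 from RNA depleted of ribosomal RNA. According to the authors, reads were aligned with STAR, counted with HTSeq and compared with DESeq2, and the genome builds GRCh38.p5 and GRCm38.p4 are both named. Versions of these tools, their options, the strand used for counting and which build served which step are not given in the sources used here. The count values are, as deposited, raw counts per gene for 15224 genes, and genes with a total under 67 over all libraries do not occur among them. The normalized signal values deposited by the authors are the counts divided by 1 size factor per library, and they were not used for tests here. The log2 values deposited by the authors are maximum-likelihood fold changes for 7 comparisons of 2 groups, without shrinkage. The p-value columns deposited by the authors hold DESeq2 p values adjusted over the genes that tool kept, and 38 to 3855 genes per comparison have none. They are given in the report beside the counts of genes called here, with the threshold of 0.05 used here.

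All tests were run on the deposited counts in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr at its minimum count of 10, which removed none of the 15224 genes. Of these, 12975 are protein-coding, 1472 are long noncoding and 777 belong to other classes, and 13016 were placed on the GRCm38 genome with GENCODE release M21. Libraries were scaled by the trimmed mean of M values, with factors from 0.91 to 1.07. Apart from the alternatives and a model of age and genotype in the 12 control libraries, every edgeR adjusted p value comes from the quasi-likelihood F-test in a model with 1 mean for each of the 6 groups, fitted to all 18 libraries with 12 residual degrees of freedom, and adjusted by the method of Benjamini and Hochberg over all genes of a comparison. Genes with an adjusted p under 0.05 are called, with no minimum fold. The biological coefficient of variation was 20.1%, with 3.94 prior degrees of freedom. Standard errors of log2 fold changes are the fold change divided by the square root of F. CPM are computed with the scaled library sizes. Counts between pairs of replicates varied 16.9 to 106 times as much as counting error alone would give, a ratio that abundant genes dominate. Counting error equals the biological coefficient of variation of 20.1% at 0.772 to 0.972 CPM, depending on the library, and 2086 genes (13.7%) have a mean below this range. Spearman correlations between replicates were 0.961 to 0.988.

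The comparisons were knockout against the average of both controls, against floxed and against Cre controls, and Cre against floxed controls, at each age. Further comparisons were old against young in each genotype and in both controls, and the interaction of knockout and age. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 39 lists tested in a comparison. A total of 41 lists of Notch and fucose genes, fibre, cell type and stress classes were fixed, and those with under 3 measured members were left out. Camera with an estimated correlation and fry were the alternatives. Overlaps of called genes were tested with Fisher's exact test, two-sided. The likeness of young knockout to old control muscle was measured by the Pearson correlation across genes of changes that share no library, with different controls on each side.

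Named genes were chosen by a rule. In the 4 comparisons of the knockout with both controls and of the ages in both controls and in the knockout, it took up to 10 called genes with the largest fold in each direction. They had at least 1 CPM in the higher group, every library of one side above every library of the other, and a symbol that is not a clone or model name. In other comparisons it took 3 per direction, or all called genes where fewer than 5 passed. In gene lists it took up to 4 members with the smallest p. Pofut1, Acta1, Notch1, Notch2, Notch3, Hes1, Hey1, Heyl, Pax7, Xist and Ddx3y were named whatever their values. The genes named in the interaction without 1 library, and those of the young knockout comparison with clone or model names, were named outside this rule after their values were seen. The comparisons, tests, lists and this rule were set before the data were examined.

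The alternatives planned in the same way were DESeq2 1.42.0 with its own size factors, edgeR with RLE factors, a fit of only the groups compared, Xist as a covariate, protein-coding genes only, an unadjusted p under 0.01 for overlaps, Spearman correlation or genes with a mean of at least 10 CPM for correlations, and leaving out each library in turn. Where a library was left out of a group of 3, the model still shared its spread with the other groups. Added after seeing the data were a filter of a mean of at least 1 CPM, robust dispersions, and tests without the genes of chromosome 1 from 120 to 140 Mb (100 genes) and of chromosome 2 from 145 to 165 Mb (170 genes). The code was tested on simulated data with the dispersions and depths of these libraries and 200 changed genes. Genes were drawn independently, without structure shared among libraries, so the rates below do not cover such structure in the real data. In knockout against both controls at 17 months it recovered 28.4, 56.7 and 89.4% of genes changed 1.5, 2 and 4-fold, and 4.92% of its calls were false. In old against young controls it recovered 46.3, 67.2 and 98.5%, with 7.84% false calls, and in knockout against floxed muscle at 17 months 17.9, 52.2 and 84.8%, with 3.74% false calls.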

Results

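Quadriceps muscle from mice of 3 genotypes was profiled by RNA sequencing at 2 and at 17 months of age, called young and old here, with 3 libraries for each of the 6 combinations and 18 libraries in all. Floxed controls carried Pofut1 alleles flanked by recombination sites and no Cre recombinase. Cre controls carried Cre under the skeletal alpha actin promoter, which is active in muscle fibres, with wild-type Pofut1. Knockout mice carried both, so that Pofut1 is deleted where Cre is active. Pofut1 encodes the enzyme that adds O-fucose to certain EGF-like repeats, including those of Notch receptors. Library totals ran from 24901936 to 31440196 counts, and Ttn, the giant sarcomere protein titin, took 14.5 to 23.6% of the counts. Values below are counts scaled to the size of the library (CPM) as mean ± SD, with n libraries, and the 2 control genotypes of an age together give n = 6. High Xist, the transcript of the inactive X chromosome, marked 3 of 9 young and 6 of 9 old libraries, with 1 of 3 in every young group and 2 of 3 in every old group.

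Pofut1 (Entrez 140484; GRCm38 chromosome 2, 153241533 to 153270247) was lower in young knockout muscle, at 9.51 ± 0.175 CPM (n = 3) against 17.2 ± 2.1 CPM in young controls (n = 6). The fold was 1.81 (log2 -0.86, SE 0.138, adjusted p = 0.0278). In old muscle it was 12.5 ± 3.33 CPM (n = 3) against 15.2 ± 2.02 CPM (n = 6), a log2 difference of -0.28 that did not pass the test (adjusted p = 0.219). The 3 old knockout libraries were not alike: replicates 17 and 45 had at most 10.6 CPM. The library labelled old knockout 40 had 16.3 CPM, inside the range of the 12 control libraries, 12.7 to 19.6 CPM. Without that library the old difference was -0.52 (SE 0.117, adjusted p = 0.0205), which is no test of Pofut1, since the library was singled out by its Pofut1 level. Every comparison with old knockout muscle below therefore holds 1 library whose Pofut1 level was that of a control. The young call of Pofut1 held in 3 of 9 fits that left out 1 library, with an adjusted p of up to 0.192 without young knockout replicate 82. Acta1, the gene of skeletal alpha actin whose promoter drives Cre, had 15760 ± 2090 CPM in young knockout muscle (n = 3) and 15790 ± 1710 CPM in young controls (n = 6).

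**Figure D1:**
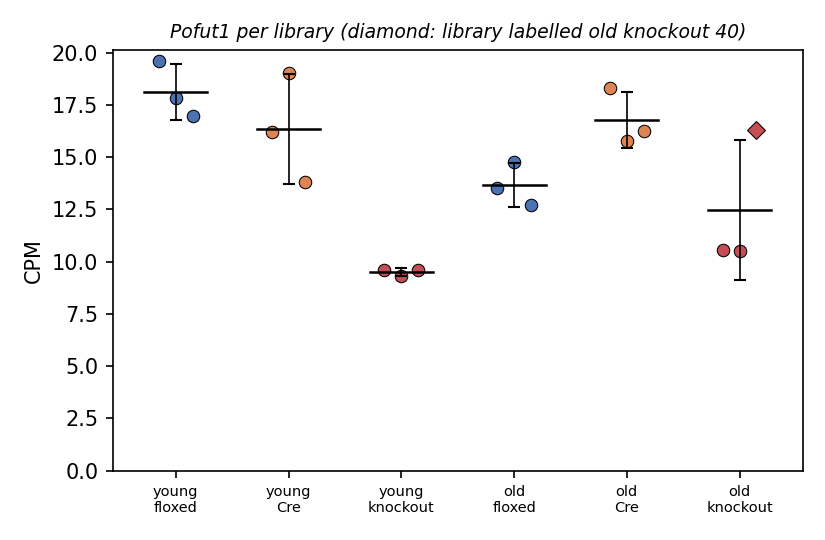
Pofut1 in CPM (vertical axis) for each of the 18 libraries, by genotype and age (horizontal axis). Points are libraries, horizontal lines are group means and error bars are SD (n = 3). The library labelled old knockout 40 (diamond, 16.3 CPM) lies among the controls, and the other 5 knockout libraries lie between 9.3 and 10.6 CPM.

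The comparison of young knockout muscle with both controls addresses what deletion of Pofut1 in fibres changes at 2 months. Few genes differed: 10 of 15224 passed the test, 7 higher and 3 lower. Beside Pofut1, the lower genes included Phlda3, a p53-induced gene, at 10.2 ± 2.08 CPM (n = 3) against 42.4 ± 13.5 CPM (n = 6; log2 -2.01, SE 0.265, adjusted p = 0.00853). The last was Ppp1r12b, a regulatory subunit of myosin phosphatase (log2 -0.70, SE 0.118, adjusted p = 0.038). Ctse, the protease cathepsin E, was 10.7-fold higher, at 1.43 ± 0.62 CPM against 0.136 ± 0.098 CPM (adjusted p = 0.0278). Chil1, a chitinase-like protein, was 9.47-fold higher, at 1.27 ± 0.283 CPM against 0.131 ± 0.0744 CPM (adjusted p = 0.00925). Lmod1, an actin-nucleating protein of smooth muscle, was 3.16-fold higher (adjusted p = 0.0248) and Dip2c 1.48-fold higher (adjusted p = 0.033). The remaining higher genes were LOC102640133, Gm8822 and E030030I06Rik.

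Several of these genes lay close together on chromosome 1: Ctse (from 131638306), Chil1 (from 134182176), Ppp1r12b (from 134754658), Lmod1 (from 135324807) and Phlda3 (from 135766119). In the window from 130 to 140 Mb, 13 of 78 genes (16.7%) had an unadjusted p under 0.01, against 2.08% of the 13011 genes placed in such windows. Without the genes of this region and of the region around Pofut1, an alternative chosen after seeing the data, 1 gene passed. The count of 10 became 67 with DESeq2 (36 higher, 31 lower) and 21 when only the young libraries were fitted. With 1 library left out it was 4 without floxed 57, 3 without Cre 93, 4 without Cre 94, 4 without Cre 61, 5 without knockout 80, 1 without knockout 82 and 4 without knockout 83. None of the 7 named genes passed in all 9 fits of this kind, Chil1 in 8, Phlda3 in 7, Ctse, Lmod1 and Pofut1 in 3, Dip2c in 1 (adjusted p up to 0.264) and Ppp1r12b in 0 (up to 0.263).

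**Figure D2:**
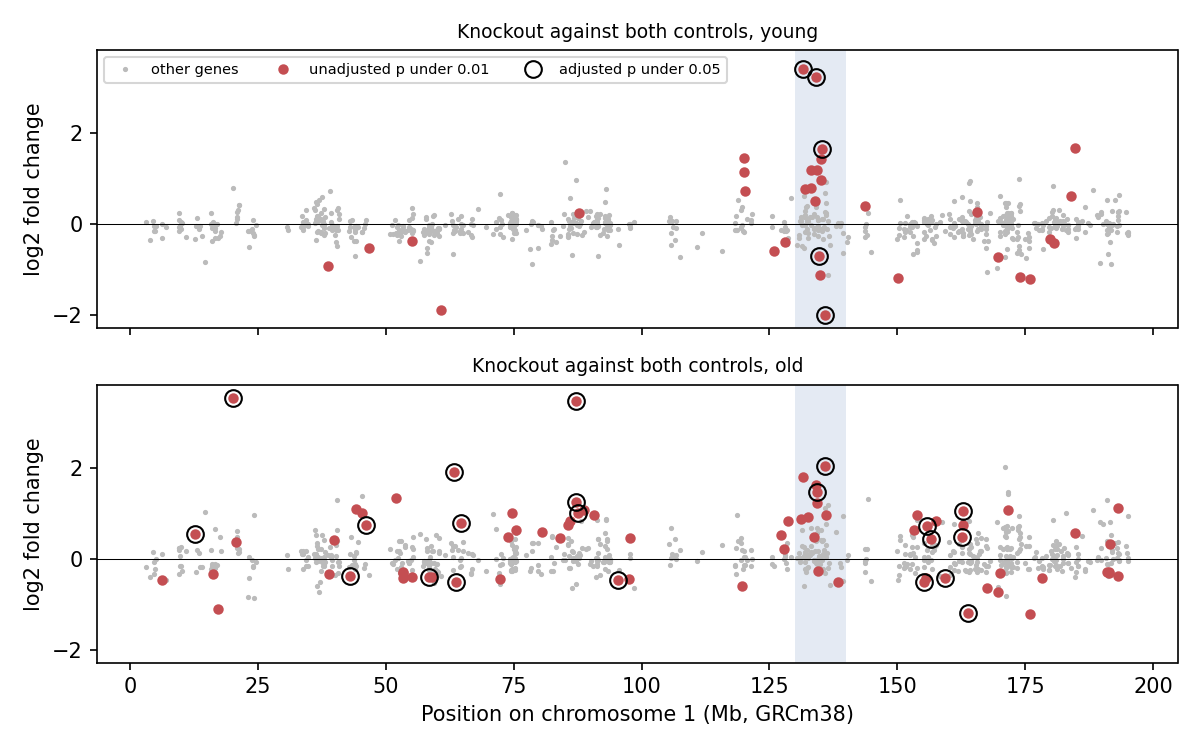
Log2 fold change of knockout against both controls (vertical axis) along chromosome 1 (horizontal axis, Mb, GRCm38), in young muscle (top) and old muscle (bottom). Each point is a gene, red points have an unadjusted p under 0.01, circles mark an adjusted p under 0.05 and the band spans 130 to 140 Mb. In young muscle 13 of the 78 genes in the band are red, and the old panel includes the library labelled old knockout 40.

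Among the 39 gene lists tested, 5 differed between young knockout and control muscle with the preset correlation of 0.01, and none with an estimated correlation (adjusted p = 0.903 for each of the 5). Of 26 interferon response genes, 24 had a negative log2 change with a median of -0.34, but none passed over all genes or adjusted over the list alone. Examples are Oas2, an antiviral synthetase (log2 -0.79, SE 0.273, adjusted p = 0.429), and Ifit1, an interferon-induced gene (log2 -0.82, SE 0.3, adjusted p = 0.46). Negative changes were also the majority among genes of the nuclear part of oxidative phosphorylation (41 of 46, median -0.13) and of the cell cycle (26 of 30, median -0.45), with no member called either way. Adipocyte genes had positive changes in 15 of 22 (median 0.37) without a call, such as Fasn, fatty acid synthase, at 160 ± 62.5 CPM (n = 3) against 49.6 ± 41.3 CPM (n = 6; adjusted p = 0.29). Of 14 smooth muscle and pericyte genes 12 had positive changes (median 0.15), and Lmod1 alone was called. The interferon call held in all 9 fits that left out 1 library. The others were called in 6 to 8 of those 9 fits, with an adjusted p of up to 0.394 for oxidative phosphorylation (without young Cre replicate 61), 0.149 for the cell cycle (without young Cre replicate 93), 0.577 for adipocytes (without young knockout replicate 83) and 0.0799 for smooth muscle (without young Cre replicate 93).

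The same comparison in old muscle had 227 genes past the test, 137 higher and 90 lower in the knockout. The higher genes included Chrnd, the delta subunit of the muscle acetylcholine receptor, at 3.28 ± 0.631 CPM (n = 3) against 1.37 ± 0.206 CPM (n = 6; 2.39-fold, adjusted p = 0.025). Among them were also Cdk6, a cell cycle kinase (2.2-fold, adjusted p = 0.00658), and Sntb1, a syntrophin of the dystrophin complex (2.24-fold, adjusted p = 0.0464). Dnah8, an axonemal dynein heavy chain (4.72-fold), Zdbf2 (3.78-fold), Prune2 (3.17-fold), Syn2, a synapsin (2.32-fold), Hs3st3b1, a heparan sulfate sulfotransferase (2.3-fold), Hhipl1 (2.28-fold) and the collagen gene Col23a1 (2.17-fold) were also higher, as the other genes named by the rule of full separation between groups. The lower genes included Aurka, a mitotic kinase, at 4.43 ± 0.7 CPM against 8.9 ± 1.74 CPM (log2 -0.99, SE 0.226, adjusted p = 0.0411). Nedd1, a centrosomal protein, was at 15.2 ± 2.76 CPM against 28.8 ± 5.06 CPM (log2 -0.92, SE 0.163, adjusted p = 0.0289). Other decreases named by that rule were in Nudt11 (log2 -1.31), Cuzd1 (-1.27), Mettl11b (-1.19), the deubiquitinase gene Usp44 (2-fold), Fam19a5 (-0.78), Ccdc50 (-0.76), Spryd7 (-0.72) and Tmem160 (-0.72). All of these directions include the library labelled old knockout 40, and none of the 20 genes passed in all 9 fits that left out 1 library (Cdk6 in 7, the others in 2 to 4). The count of 227 fell to 6 without old floxed 48, 14 without floxed 46, 13 without Cre 99, 7 without Cre 35, 1 without knockout 17 and 2 without knockout 45. It reached 1009 without floxed 5, 900 without Cre 34 and 1040 without the library labelled old knockout 40. The count was 2 when only the old libraries were fitted, 362 with Xist as a covariate and 1042 with DESeq2, where the balance turned to 483 higher and 559 lower.

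Some genes of immature and regenerating fibres were called higher in old knockout than in old control muscle. Of 22 measured members of that list, 9 passed and were higher, and 14 were higher when adjusted over the list alone. All 22 had a positive change, with a median of 1.15. Myh3, embryonic myosin heavy chain, had 105 ± 113 CPM (n = 3) against 14.3 ± 7.41 CPM (n = 6; log2 3.02, SE 0.595, adjusted p = 0.0338). Myh8, perinatal myosin heavy chain, had 181 ± 173 CPM against 36.1 ± 10.3 CPM (log2 2.35, adjusted p = 0.0289). Myl4, an embryonic and atrial myosin light chain, was 6.38-fold higher (adjusted p = 0.0349) and Igf2, a fetal growth factor, 5.43-fold higher (adjusted p = 0.0349). The increase lay in replicates 17 and 45: Myh3 was 69.8 and 232 CPM there, 13.8 CPM in the library labelled old knockout 40, and 6.9 to 25.7 CPM in the 6 old controls. The list was called in all 9 fits that left out 1 library with the preset correlation, but not with an estimated correlation (adjusted p = 0.555) or with fry (0.104). Against old Cre controls alone no member passed over all genes (Myh3 0.247, Myh8 0.173, Myl4 0.217, Igf2 0.213), and 12 were higher when adjusted over the list alone.

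Some genes that rise on loss of nerve contact, acetylcholine receptor genes among them, were also called higher. In the denervation list 5 of 25 genes passed and were higher, and 13 were higher and 1 lower when adjusted over the list alone (median 0.76), but not as a list with an estimated correlation (adjusted p = 0.626). Chrng, the fetal gamma subunit, was 11.2-fold higher (1.25 ± 1.27 CPM, n = 3, against 0.169 ± 0.147 CPM, n = 6; adjusted p = 0.0391). Chrna1, the alpha subunit, was 2.13-fold (adjusted p = 0.0381) and Ncam1, a cell adhesion molecule, 2.75-fold higher (adjusted p = 0.0401). In the library labelled old knockout 40 these 3 lay within the range of the old controls (Chrng 0.118 CPM, Chrna1 18.9 CPM, Ncam1 7.17 CPM). The receptor gene Chrnd lay above that range in this library, at 2.55 CPM against 1.1 to 1.69 CPM in old controls. Against old Cre controls alone only LOC102640133 and Tns3 passed. Neither Chrnd nor any other gene named in this or the next paragraph did. In the neuromuscular junction list 3 of 20 passed and were higher, 8 when adjusted over the list alone (fry 0.0122, adjusted p = 0.555 with an estimated correlation). Among them were Chrnd, Chrna1 and Ank3, an ankyrin (log2 0.58, adjusted p = 0.0361). In the dystrophin complex and laminin list 4 of 23 passed and were higher, and 7 were higher and 2 lower when adjusted over the list alone (fry 0.0188, adjusted p = 0.555 with an estimated correlation). They were the laminin chains Lama2 (1.61-fold) and Lamb1 (1.79-fold), the integrin Itga7 (1.44-fold) and Sntb1. The last list carried by fry was that of Notch targets, with no gene called over all genes or over the list alone (fry 0.0481, adjusted p = 0.209 with the preset and 0.626 with an estimated correlation).

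**Figure D3:**
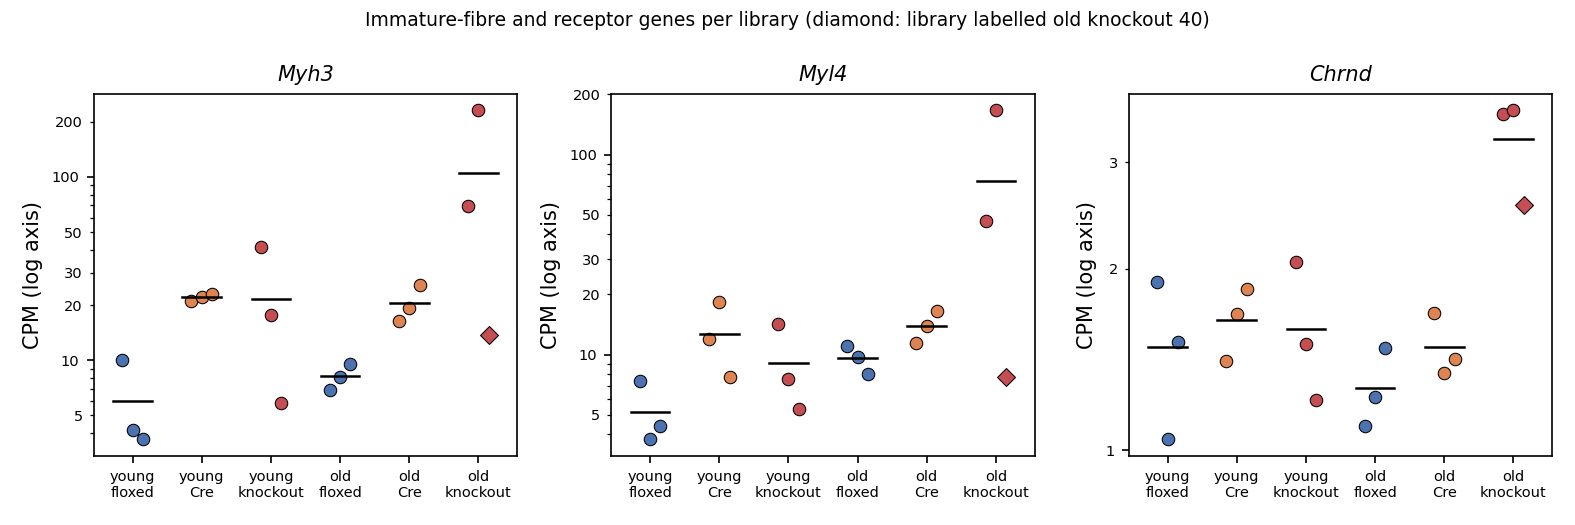
CPM on a log axis (vertical) of Myh3, Myl4 and the acetylcholine receptor gene Chrnd in each of the 18 libraries, by genotype and age (horizontal). Points are libraries and horizontal lines group means (n = 3). Old knockout replicates 17 and 45 stand highest for Myh3 and Myl4. The library labelled old knockout 40 (diamond, Myh3 13.8 CPM) lies within the range of the old controls for Myh3. For Chrnd it lies above them (2.55 CPM against 1.1 to 1.69 CPM).

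Extracellular matrix genes had positive changes in 38 of 41 members in old knockout against old control muscle (median 0.62), but 1 passed over all genes, and 22 were higher and 1 lower when adjusted over the list alone. That gene was Bgn, the proteoglycan biglycan, at 30.3 ± 11.2 CPM (n = 3) against 14.7 ± 0.696 CPM (n = 6; adjusted p = 0.0289). The matrix list was called in all 9 fits that left out 1 library, though not with an estimated correlation (adjusted p = 0.626). In the fibro-adipogenic list 2 of 18 passed (4 adjusted over the list alone), Fbln2, a matrix protein (1.62-fold, adjusted p = 0.0289), and Pdgfra, a receptor that marks these cells (1.57-fold, adjusted p = 0.0338). That list had an adjusted p = 0.656 with an estimated correlation and 0.127 with the preset without old knockout 17. Macrophage genes had positive changes in 23 of 24 without a call (median 0.60; adjusted p = 0.704 with an estimated correlation), and the list's preset call ended without old knockout replicate 45 (adjusted p = 0.735). The cell cycle list was called upward (25 of 30 positive, median 0.70), while its 1 called gene, Aurka, was lower, and 4 were higher and 2 lower when adjusted over the list alone (adjusted p = 0.704 with an estimated correlation, and 0.231 with the preset without old knockout 45). Genes of nuclear oxidative phosphorylation were negative in 44 of 46 without a call (median -0.18; adjusted p = 0.704 with an estimated correlation, and 0.0752 with the preset without old knockout 17). Satellite cell genes (1 of 23 called, Itga7, and 3 adjusted over the list alone), Schwann cell genes (0 of 14, and 1) and antigen presentation genes (0 of 4, and 2) were the other lists with a preset call upward, each with an adjusted p = 0.626 with an estimated correlation. Their preset calls ended without old knockout 45 (0.634), without the library labelled old knockout 40 (0.492) and without old knockout 45 (0.328), in that order.

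Comparisons with each control alone separate Cre in floxed animals from floxed alleles in Cre animals. Against floxed controls, 1 gene passed in young muscle, Cd28, a T cell costimulatory receptor, at 0.099 ± 0.0254 CPM against 0.991 ± 0.231 CPM (n = 3 each; adjusted p = 0.0278, or 0.266 without young knockout 83). Cd28 was also low in young Cre controls (0.0747 to 0.24 CPM), so this call is not particular to the knockout. Against Cre controls 2 passed, Phlda3 (lower, log2 -2.35, adjusted p = 0.00354, or 0.0873 without young knockout 80) and LOC102640133, at 11 ± 1.08 CPM against 2.13 ± 0.364 CPM (adjusted p = 4.46e-07). In old muscle 570 genes passed against floxed controls, 268 higher and 302 lower. They included Chrng (at 1.25 ± 1.27 CPM against 0.0366 ± 0.0354 CPM), the large membrane protein gene Pkhd1 (25.3-fold) and Myh3 (12.8-fold) upward, and downward Rn7s1, a signal recognition particle RNA (log2 -1.64), Serpinb1c (-1.56) and Tpx2, a spindle protein (-1.54). Chrng, Pkhd1 and Myh3 were also higher in Cre than in floxed controls when both ages were fitted together (log2 2.82, 2.32 and 1.60) and did not pass against old Cre controls. Pkhd1 was at 3.07 and 9.4 CPM in replicates 17 and 45, and at 0.196 CPM in the library labelled old knockout 40, beside 0.142 to 0.195 CPM in old floxed muscle. Against old Cre controls 2 passed, LOC102640133 (5.54-fold) and Tns3, a focal adhesion protein, at 23.4 ± 2.67 CPM against 13.2 ± 1.36 CPM (adjusted p = 0.0099, or 0.097 without old knockout 17). The 570 became 1 without old floxed 48, 0 without floxed 46, 1947 without floxed 5, 0 without knockout 17, 0 without knockout 45, 1438 without the library labelled old knockout 40 and 0 when only these groups were fitted (3012 at an unadjusted p under 0.05). The comparison with old Cre controls rose from 2 to 128 without that library. With DESeq2 the counts were 44, 47, 1751 and 120, and the authors' own adjusted p values called 36, 48, 1719 and 130 genes, of which 1, 2, 555 and 2 were also called here.

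Between the 2 control genotypes, LOC102640133 was lower in Cre than in floxed muscle at both ages, at 2.13 ± 0.364 CPM against 12.7 ± 0.673 CPM in young (n = 3 each; log2 -2.57, adjusted p = 1.24e-07) and at 2.4 ± 0.282 CPM against 16.1 ± 1.47 CPM in old muscle (log2 -2.75, adjusted p = 4.26e-08). The other genes called were Cd28 in young (0.14 ± 0.0882 against 0.991 ± 0.231 CPM, adjusted p = 0.0489) and Sox12, a transcription factor gene, in old muscle (0.169 ± 0.0614 against 0.804 ± 0.181 CPM, adjusted p = 0.043). DESeq2 called 19 genes in young and 24 in old muscle. Cd28 and Sox12 were each called in 1 of 6 fits that left out 1 library, with an adjusted p of up to 0.276 without young Cre replicate 94 and 0.384 without old floxed replicate 46.

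Ageing, which here means the difference between 17 and 2 months, gave the most calls in both controls together. In all, 2763 genes passed (6 libraries at each age), 1228 higher and 1535 lower in old muscle. Other comparisons of 2 sides had 3 libraries on at least 1 side. With 3 on each side, ageing gave 1605 calls in floxed and 274 in Cre muscle, and old knockout against floxed muscle gave 570. Samples of 2 ages do not show when between them a change arose, during growth or later. The labels name no batch or litter, so a batch that went with age could not be told from age. Immunoglobulin genes were among the largest increases. Igkc, the kappa constant region, rose from 0.101 ± 0.0649 to 9.62 ± 11.5 CPM (adjusted p = 0.00245). Igj, the joining chain, rose 14.7-fold (adjusted p = 0.00438), and Ighv1-53 rose from no count in the 6 young libraries to 1.17 ± 0.737 CPM (adjusted p = 0.00775). Ostn, a peptide secreted by muscle, rose from 2.29 ± 0.626 to 52.9 ± 33.3 CPM (22.9-fold, adjusted p = 7.68e-05). Dkk3, a Wnt-related secreted protein (7.96-fold), Mss51 (6.48-fold), Rasd2 (5.79-fold), Rhpn2 (4.73-fold), Mustn1 (4.5-fold) and Apol11b (8.44-fold) followed. The decreases included Actc1, cardiac alpha actin, which is expressed in developing skeletal muscle, from 717 ± 117 to 57.1 ± 33 CPM (log2 -3.70, SE 0.429, adjusted p = 9.26e-05). Col1a1, a fibrillar collagen, fell from 144.8 ± 47.8 to 11.8 ± 2.5 CPM (log2 -3.62, SE 0.411, adjusted p = 9.26e-05). Fbn2, a fibrillin (log2 -3.13), Col11a1 (-2.93), Bcat1 (-2.84), Col1a2 (-2.79), Nrk (-2.75), Ttyh1 (-2.74), Wisp1 (-2.59) and Cilp2 (-2.51) fell as well. Of the 23 named genes called in this comparison, 20 passed in all 12 fits that left out 1 library. The others were Apol11b (adjusted p = 0.0866 without old Cre 99), Heyl (0.13 without old floxed 46) and Pax7 (0.0525 without old Cre 99). The count of 2763 moved by over 1.5 times only without old floxed 46, to 1816.

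Genes of the extracellular matrix fell together with age. Of 41 measured members 33 passed and were lower, and 36 were lower when adjusted over the list alone. The median log2 change was -1.26 (fry 3e-04, adjusted p = 0.0945 with an estimated correlation). Col4a1, a basement membrane collagen, fell from 169 ± 19.5 to 58.5 ± 14.3 CPM (n = 6 each; adjusted p = 7.82e-05), and the crosslinking enzymes Lox and Loxl2 fell 2.96-fold and 3.57-fold. Tendon genes were lower in 7 of 10 (9 adjusted over the list alone; median -1.09; fry 3e-04, adjusted p = 0.0945 with an estimated correlation), such as Tnmd, tenomodulin (3.56-fold lower), and Kera, a corneal and tendon proteoglycan (2.96-fold lower). Fibro-adipogenic genes were lower in 13 of 18, over all genes and over the list alone, by less (median -0.45; fry 0.000783, adjusted p = 0.229 with an estimated correlation), with Pdgfra at 59.3 ± 9.23 CPM against 91.2 ± 9.33 CPM. Growth factor genes were lower in 5 of 23 and higher in 1 (the same adjusted over the list alone; fry 0.000935, adjusted p = 0.254 with an estimated correlation), led by Igf1, insulin-like growth factor 1 (4.04-fold lower). In the dystrophin complex and laminin list 10 of 23 were lower and 1 higher, 10 and 4 when adjusted over the list alone (fry 0.00615, adjusted p = 0.525 with an estimated correlation). Without old floxed 46 the preset calls of these last lists ended (adjusted p = 0.0753 and 0.0808).

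**Figure D4:**
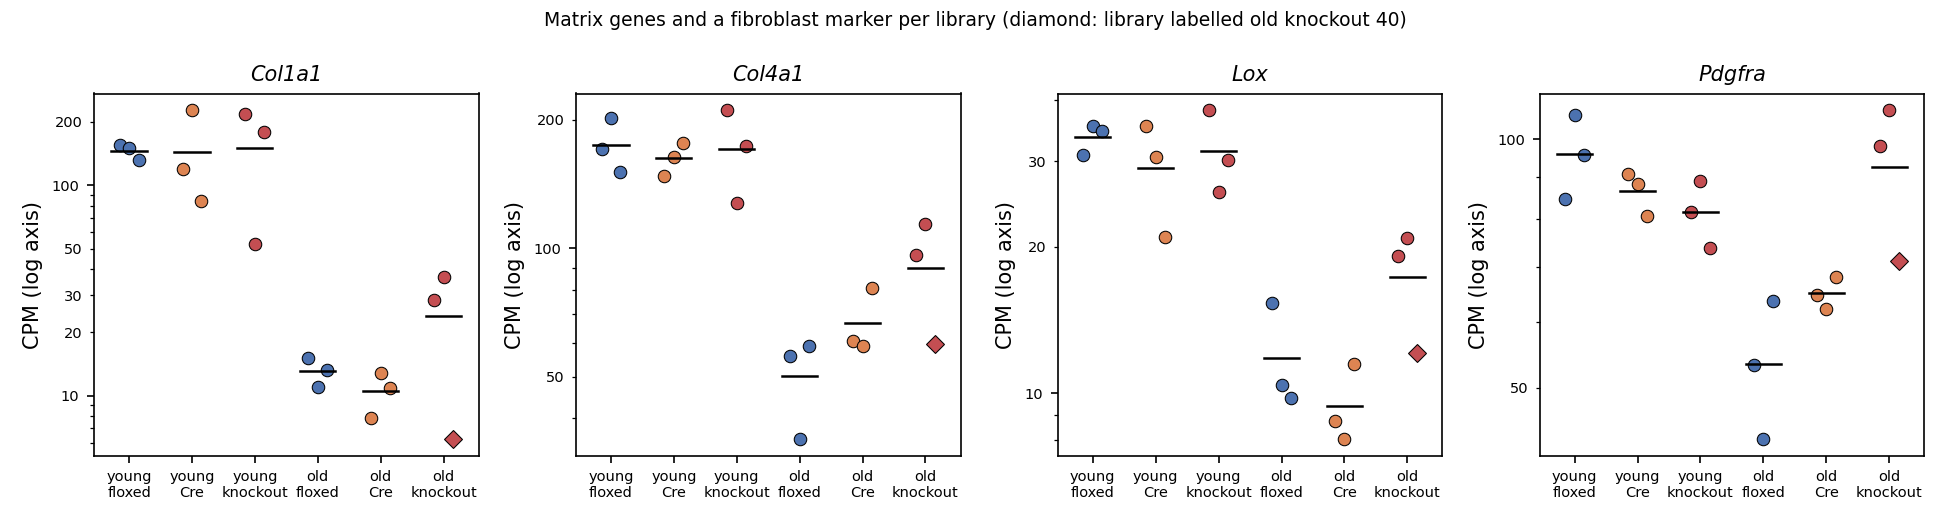
CPM on a log axis (vertical) of Col1a1, Col4a1 and Lox of the extracellular matrix and of Pdgfra, a marker of fibro-adipogenic cells, in each of the 18 libraries, by genotype and age (horizontal). Points are libraries and horizontal lines group means (n = 3). Col1a1 fell from 144.8 to 11.8 CPM between young and old controls and Pdgfra from 91.2 to 59.3 CPM, and the diamond is the library labelled old knockout 40.

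Markers of several other cells also differed with age in controls. B and plasma cell genes were higher in 6 of 11 (10 adjusted over the list alone; fry 0.00824, adjusted p = 0.295 with an estimated correlation), for example Ighg2c, at 12.5 ± 9.14 CPM against 0.629 ± 0.455 CPM (n = 6 each). Interferon response genes were lower in 7 of 26 (10 adjusted over the list alone; median -0.51; fry 0.0212, adjusted p = 0.591 with an estimated correlation), such as Gbp7, a guanylate-binding protein (2.9-fold lower). Satellite cell genes were lower in 7 of 23 (9 lower and 1 higher adjusted over the list alone; fry 0.00615, adjusted p = 0.439 with an estimated correlation). Megf10 was 2.6-fold lower, and Pax7, the transcription factor of these cells, was at 0.677 ± 0.2 CPM against 1.32 ± 0.269 CPM (adjusted p = 0.0219, or 0.0525 without old Cre 99). Schwann cell and myelin genes were lower in 4 of 14, over all genes and over the list alone (fry 0.0192, adjusted p = 0.591 with an estimated correlation), led by Pmp22, a myelin protein (1.83-fold lower). Slow fibre genes were positive in 19 of 19, with 3 called over all genes and over the list alone (adjusted p = 0.808 with an estimated correlation): Fhl1 (3.02-fold), Mybpc1 (1.48-fold) and Myom3 (1.92-fold). Cytosolic ribosomal protein genes were positive in 38 of 40, with 9 called and 12 adjusted over the list alone (median 0.20; adjusted p = 0.808 with an estimated correlation). Endothelial (3 of 19 lower, 5 adjusted over the list alone), complement (3 of 13 lower, and 5) and cell cycle genes (3 of 30 lower and 1 higher, and 5 and 1) were the remaining lists with a preset call, each with an adjusted p = 0.808 with an estimated correlation. The preset call ended without young Cre 93 for the complement and cell cycle lists (adjusted p = 0.128 for both).

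Within a single control, 1605 genes passed with age in floxed muscle (674 higher, 931 lower) and 274 in Cre muscle (122 higher, 152 lower). Actc1 was lower in both, from 681 ± 62.4 to 42 ± 33.9 CPM in floxed and from 753 ± 163 to 72.1 ± 29.7 CPM in Cre muscle (n = 3 each; adjusted p = 0.0133 in Cre muscle, or 0.0699 without old Cre 99). In floxed muscle Ucp1, the uncoupling protein of brown fat, was lower in old muscle, at 0.125 ± 0.0422 CPM against 30.3 ± 50.4 CPM (adjusted p = 0.0169, or 0.174 without young floxed 92), as was the carboxylesterase gene Ces1f (log2 -3.94, adjusted p = 0.0301, or 0.296 without young floxed 92). The immunoglobulin genes Ighv1-53, Igkc and Ighg2c were among the increases in floxed muscle, and Ostn, Dkk3 and Rasd2 in Cre muscle, where Col1a1 (13.7-fold) and Col11a1 (7.77-fold) were lower. The floxed count was 663 without young floxed 57, 883 without young floxed 92, 809 without old floxed 48 and 413 without old floxed 46, where the immunoglobulin calls Ighv1-53 and Igkc ended (adjusted p = 0.161 and 0.146). Ighg2c was called in 1 of 6 fits that left out 1 library, with an adjusted p of up to 0.0719 without young floxed 57. The Cre count was 65 without young Cre 93, 166 without young Cre 94, 156 without young Cre 61, 41 without old Cre 99, 159 without old Cre 35 and 65 without old Cre 34. The authors' adjusted p values called 2270 and 656 genes, 1578 and 272 of them also called here.

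In knockout muscle 166 genes passed with age, 84 higher and 82 lower (n = 3 each, with the library labelled old knockout 40 among the old ones). Ostn rose 12.6-fold (adjusted p = 0.0171), from 2.01 ± 0.592 to 25.4 ± 12.8 CPM, and the chemokine gene Cxcl13 from 0.0833 ± 0.0787 to 1.12 ± 1.05 CPM (adjusted p = 0.0489). Cacna1i, a calcium channel (1.07 ± 0.128 against 0.111 ± 0.038 CPM), Uchl1, a ubiquitin hydrolase of neurons (8.49-fold), Aox3 (6.18-fold), Rasd2 (5.67-fold), Dkk3 (4.82-fold), Lrrc52 (4.52-fold), Mustn1 (4.35-fold) and Srrm4os (4.14-fold) were higher too. Col1a1 fell from 150 ± 87 to 23.8 ± 15.8 CPM (log2 -2.65, SE 0.554, adjusted p = 0.0301). Lower as well were Sfrp2, a Wnt antagonist (log2 -2.10), Col11a1 (-1.99), Nrk (-1.94), Slc2a10 (-1.88), Acly, ATP citrate lyase (-1.83), Olfr78 (-1.83), Ret, a receptor kinase (-1.73), Hunk (-1.68) and Nrep (-1.66). Matrix genes were lower in 3 of 41 (16 adjusted over the list alone; median -0.62; adjusted p = 0.657 with an estimated correlation) and tendon genes in 2 of 10 (9 adjusted over the list alone; median -0.83; fry 0.0177, adjusted p = 0.101 with an estimated correlation). Regeneration genes had positive changes in 19 of 22, with 1 called, Myh8, and 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.657 with an estimated correlation, and a preset call that ended without old knockout 45, adjusted p = 0.166). The denervation, neuromuscular junction, slow fibre, B and plasma cell, ribosomal, cell cycle and atrophy lists had a preset call upward and the smooth muscle, adipocyte and fibro-adipogenic lists downward, none with an estimated correlation (adjusted p = 0.657 to 0.847), and with 0 to 8 members called when adjusted over the list alone. In these lists Map1lc3a, an autophagy gene (adjusted p = 0.0477), and Des, desmin (adjusted p = 0.019), were called higher and Lmod1 lower (adjusted p = 0.0489). The fibro-adipogenic call ended without the library labelled old knockout 40 (0.469) and the denervation, ribosomal and cell cycle calls without old knockout 45 (0.0632, 0.166 and 0.553). The adipocyte and neuromuscular calls ended without young knockout 83 (0.446 and 0.0928). Of the 20 named genes, Cacna1i and Rasd2 passed in all 6 fits that left out 1 library. The count of 166 was 18 without young knockout 80, 70 without young knockout 82, 23 without young knockout 83, 68 without old knockout 17, 99 without old knockout 45, 10 when only these groups were fitted, and 497 with DESeq2. The authors' adjusted p values called 504 genes, 164 of them also called here.

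The ageing calls of knockout and controls overlapped: 57 genes were higher in both (6.78 by chance, Fisher's exact p = 1.27e-42, two-sided) and 59 lower in both (8.27 by chance, p = 7.71e-41 in the same exact test), with 0 in opposite directions. The knockout calls at the 2 ages shared 1 higher gene, LOC102640133 (0.063 by chance, Fisher's exact p = 0.0613), and 0 lower genes. This call rests on the low Cre controls (2.13 and 2.4 CPM), since the knockout was not above floxed muscle (11 against 12.7 CPM in young, 13.3 against 16.1 CPM in old muscle). Across genes, which are not independent replicates, the log2 changes correlated at 0.513 for ageing in knockout and controls and at 0.206 for the knockout at the 2 ages. The difference between knockout effects at the 2 ages was tested as an interaction in edgeR, and 0 genes passed (1714 at an unadjusted p under 0.05, 77 adjusted with DESeq2, and 13 with edgeR without the library labelled old knockout 40). In the fit without that library Myh8, Igf2, Pdgfra and Zdbf2 were among the 13. With Xist as a covariate 3 genes passed in edgeR with all libraries.

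Whether young knockout muscle resembles old control muscle was asked with log2 changes that share no library. Young knockout against young floxed muscle correlated with ageing in Cre muscle at 0.199 across genes, and young knockout against young Cre muscle with ageing in floxed muscle at 0.0775 (Spearman 0.211 and -0.0345). Splits of the 6 young libraries other than by genotype reached 0.277 and 0.218, so neither value exceeded what regrouped libraries gave. The 152 genes lower with age in Cre muscle had a median of -0.19 in the first comparison (camera p = 1.12e-07 with the preset and 0.163 with an estimated correlation), and the 931 genes lower with age in floxed muscle a median of 0.05 in the other (p = 0.0476 and 0.605).

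Genes of the Notch pathway, the best known substrates of Pofut1, did not pass in either knockout comparison with both controls with all libraries. Notch1 was at 11.2 ± 2.23 CPM in old knockout (n = 3) against 8.16 ± 1.77 CPM in old control muscle (n = 6; adjusted p = 0.132), and its log2 change in young muscle was 0.27 (adjusted p = 0.704). The log2 changes of Notch2 were 0.16 in young (adjusted p = 0.824) and 0.62 in old muscle (adjusted p = 0.0626). Against old floxed controls alone Notch2 passed, at 34.7 ± 6.17 CPM against 20.1 ± 4.47 CPM (n = 3 each; adjusted p = 0.0406), but not against old Cre controls (log2 0.44, adjusted p = 0.342). That call ended without old floxed 48, floxed 46, knockout 17 or knockout 45, and when only these groups were fitted. Without the library labelled old knockout 40 Notch2 also passed against both controls (log2 0.74, adjusted p = 0.024). The changes of Hes1, a Notch target, were 0.45 (adjusted p = 0.593) and -0.23 (adjusted p = 0.552), and those of Hey1, another target, were -0.56 (adjusted p = 0.56) and 0.37 (adjusted p = 0.372). Notch3 and Heyl had adjusted p values of 0.922 and 0.915 in young and 0.964 and 0.916 in old muscle. With age in controls Hey1 fell (log2 -0.81, SE 0.198, adjusted p = 0.0111), and Heyl passed narrowly (log2 -0.71, adjusted p = 0.0497, or 0.13 without old floxed 46). Of 22 Notch target genes 4 were lower and 1 higher with age, over all genes and over the list alone (fry 0.00129, adjusted p = 0.166 with the preset). Of 23 receptor, ligand and processing genes 4 were lower and 2 higher, 7 and 3 when adjusted over the list alone (adjusted p = 0.872 with the preset, toward lower values as in the median of -0.11, with a mean of 0.00167). In the fucose pathway list Pofut1 alone was called in young knockout muscle, over all genes and over the list alone, of 17 measured (adjusted p = 0.943 with the preset, toward lower values with a median of 0.06), and no member in old knockout muscle. Without the library labelled old knockout 40, Fut11, a fucosyltransferase (log2 0.62, adjusted p = 0.0369), passed there beside Pofut1, by which that library was singled out.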

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

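The tests of the crowding of genes on chromosome 1 and of their shift in old libraries, and the comparison of matrix genes with cell markers, used against fewer fibroblasts and against a few genes taking most counts, were chosen after the results were seen.

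The interaction of knockout and age called 9 of 39 gene lists with the preset correlation and none with an estimated correlation (adjusted p = 0.758 for each). In all 9 the change in the knockout leaned toward more positive values at 17 than at 2 months: regeneration, extracellular matrix, cell cycle, macrophages, fibro-adipogenic cells, denervation, interferon response, neuromuscular junction and satellite cells. The largest medians were 1.15 for the cell cycle and 1.02 for regeneration. A negative change in young knockout enters some of them: the medians at 2 months were -0.34 for interferon response genes, not called at 17 months (median 0.11, adjusted p = 0.895 with the preset), and -0.45 for the cell cycle. None was called with fry, and 78 of 100 splits of the libraries within age, the real one among them, gave at least 9 lists (highest other 20), so chance is not excluded.

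One pattern is the crowding of genes called in young knockout muscle on chromosome 1, from 130 to 140 Mb. An inherited segment of another strain would place changed genes side by side. In 1000 shuffles of the genes over their positions no window was as crowded (0.001, the smallest value they can give). Crowding alone does not identify a segment, since ageing within Cre muscle also gave it (chromosome 1, 40 to 50 Mb, 10 of 31 genes, 0.006). A segment tied to the Cre transgene or the floxed alleles would be shared by 1 of the control genotypes. Against that, 12 of 78 genes in the window had an unadjusted p under 0.01 against young floxed controls, and 11 of 78 against young Cre controls. The genes called there, Chil1, Ctse, Lmod1, Phlda3 and Ppp1r12b, may still differ by inheritance. A response to loss of Pofut1 at both ages would shift the same genes in old knockout libraries. Their mean shift there was 0.722 ± 0.431 (n = 3), against 1.99 ± 0.181 in young ones (n = 3). The genes were chosen for their call in young muscle, which favours a larger shift there. By gene, the old log2 changes were 1.81 for Ctse and 1.62 for Chil1 (3.42 and 3.24 in young). They were 0.386 for Lmod1, -0.307 for Phlda3 and 0.0574 for Ppp1r12b (1.66, -2.01 and -0.698 in young). The mean in old muscle thus rested mostly on Ctse and Chil1. Of the old knockout libraries, only the one labelled 40, which has Pofut1 at control level, had a mean shift above 0.996, the bound set for the test. Scored against all controls (-0.316 to 0.337), it had 1.12, and replicates 17 and 45, with low Pofut1, had 0.86 and 0.275. The shift thus did not follow the level of Pofut1 in these 3 libraries. They are too few to decide, so this explanation stays open, as does a segment that some old animals lack.

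Another pattern is the control level of Pofut1 in the library labelled old knockout 40. A swap with a Cre control is argued against by 23 genes that separate the controls, on which it scored 0.918, with floxed libraries at 0.851 to 1.04 and Cre libraries at -0.0876 to 0.12. The same control libraries chose these genes and set the 0 and 1 of the score, so the gap between the control ranges was built in. Knockout libraries, including the one labelled old knockout 40, had no part in that choice. The other 5 knockout libraries scored 0.0162 to 0.531 on these genes. A floxed animal without Cre stays open: between old floxed libraries (0) and the other old knockout libraries (1) it scored 0.375, and floxed libraries left out in turn scored -0.0852 to 0.46. Old Cre controls scored 0.275 to 0.582 there, so this score does not tell loss of Pofut1 from other differences to floxed muscle. Incomplete deletion also stays open, since its score did not exceed 0.46, yet an animal with inactive Cre would score like a floxed one, so the bound written for that test was wrong by design. Myh3 (13.8 CPM), Chrng (0.118 CPM) and Tnnt2 (3.57 CPM) lay within the range of the old controls in this library, and the genes called on chromosome 1 above it, as given in the paragraph before. By genotype, Myh3 lay between the old floxed (6.9 to 9.58 CPM) and old Cre libraries (16.5 to 25.7 CPM). Chrng did too (0 to 0.0708 and 0.281 to 0.314 CPM), while Tnnt2 lay among the old floxed libraries (3.08 to 3.64 CPM). Tns3 (21.4 CPM, old controls 11.6 to 15.1 CPM) and Nedd1 (18.2 CPM, old controls 21.5 to 34.5 CPM) lay on the knockout side, but both were named for differing with this library counted as a knockout, so they do not decide its origin.

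The last pattern is the fall of matrix genes in old controls. Fewer fibroblasts, lost evenly, would lower matrix genes and markers of fibro-adipogenic cells alike. Instead 38 matrix genes fell by more than 15 markers (-1.26 and -0.487), a difference of -0.776 (exact permutation p = 0.00216, n = 6 libraries each, the smallest that 924 splits can give). This argues against an even loss as the whole cause only if the markers follow cell number, which was not measured. Loss of some of these cells, or of tendon cells, whose genes also fell, was not tested. The larger number of libraries with high Xist among old animals is argued against by a median of -1.22 with Xist as a covariate. A few genes taking most counts would change the scale of all genes alike and leave matrix and marker genes together, so the same difference of -0.776 argues against it as the whole cause. The test first planned for it, the median without the 10 most abundant genes (-1.26), adds nothing, since the scaling trims such genes already. A lower matrix transcription per cell with age is a candidate explanation and was not tested.

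Other splits of the libraries were used to ask where chance can be excluded. The numbers of splits given here include the real split, so 1 means that no other split reached its count. With both controls as 1 group, 1 of 100 splits gave as many ageing genes as the real one (2739, highest other 516). As many young knockout genes (9, highest other 28) came from 4 of 84 splits. As many old knockout genes (198) came from 3 of 84. Each share is under 0.05, but none was adjusted for the number of tests of this kind. At that unadjusted level chance is excluded for ageing, where no other split came near the real count. A batch that went with age would give the same result, and the splits cannot tell it from age. For the knockout at both ages other splits called more genes, so these counts are borderline and chance is not firmly excluded. Several genes called in young knockout muscle also lie close together on chromosome 1, so they are not independent. The highest other split of the old libraries called 1207 genes, several times the real count. It set Cre 34 with knockout 17 and 45, and so the library labelled old knockout 40 among the controls. With the real labels, leaving out 1 library gave 1040 genes without that library, 1009 without floxed 5 and 900 without Cre 34. The split points to a structure of the samples, and these counts do not single out the library that makes it. For gene lists, 80 of 84 splits in young knockout (5 lists, highest other 16), 49 of 84 in old knockout (12, highest other 21) and 16 of 100 in ageing (15, highest other 22) gave as many, so chance is not excluded. For the interaction of single genes all 100 splits reached the real count of 0, and the highest other was 584.

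The 10 splits of 3 against 3 libraries are too few for a share under 0.05. Here too the real split is counted among them. As many genes as the real split were given by 1 split in knockout against floxed at 2 months (1 gene, highest other 0), 1 in knockout against Cre at 2 months (2, other 0), 1 in knockout against floxed at 17 months (570, other 6) and 2 in knockout against Cre at 17 months (2, other 142). The 142 genes separated Cre 99, Cre 35 and the library labelled old knockout 40 from Cre 34, knockout 17 and knockout 45. For Cre against floxed it was 2 splits at 2 months (2, other 2) and 1 at 17 months (2, other 1). For ageing it was 1 split each in floxed (1605, other 1), Cre (274, other 0) and knockout muscle (166, other 13). For the correlations it was 3 splits (0.199, other 0.277) and 6 splits (0.0775, other 0.218).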

How the results depend on the processing

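The filter at a mean of at least 1 CPM, robust dispersions and the fit without the 2 chromosome segments were chosen after the results were seen. Counts within 1.5 times the reported one are not listed, and the cause of the changes below was not tested unless given.

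With DESeq2 in place of edgeR the counts of genes were 67 for the knockout against both controls at 2 months and 1042 at 17 months, 44 and 1751 against floxed, 47 and 120 against Cre, 19 and 24 between the controls, 678 for ageing in Cre, 497 in knockout muscle and 77 for the interaction. With only the groups compared, which leaves fewer libraries to estimate the spread, they were 21 and 2 against both controls, 9 and 0 against floxed, 17 and 1 against Cre, 1 between young controls, 97 for ageing in Cre and 10 in knockout muscle. With Xist as a covariate they were 362 for old knockout against both controls, 4 and 871 against floxed, 4 and 4 against Cre, 1 and 1 between the controls, and 3 for the interaction. With protein-coding genes only, which leaves out LOC102640133, they were 1 and 1 against Cre and 0 and 0 between the controls, where the calls of Cd28 and Sox12 ended too. The filter at 1 CPM gave 6 for young knockout against both controls, 0 against floxed, and 1 and 1 between the controls, robust dispersions 1 and 1 between the controls, and the fit without the 2 segments 1 for young knockout.

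With 1 library left out the counts ran from 1 to 14 and 1 to 1040 against both controls (2 months, 17 months), 0 to 6 and 0 to 1947 against floxed, 1 to 2 and 1 to 128 against Cre, and 1 to 2 and 1 to 7 between the controls. For ageing they ran from 413 to 2267 in floxed, 41 to 166 in Cre, 1816 to 2951 in both controls and 18 to 237 in knockout muscle, and for the interaction from 0 to 13. Gene lists called ran from 3 to 10 in young knockout, 8 to 18 in ageing of the knockout and 7 to 14 for the interaction.

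With an estimated correlation 0 lists were called in any of 5 comparisons, where the preset called 5 and 12 (knockout at 2 and 17 months), 14 and 13 (ageing in controls and knockout) and 9 (interaction). Fry called 0, 3, 10, 1 and 0. The correlation of young knockout with ageing was 0.199 over all genes, 0.319 over genes of at least 10 CPM, and 0.107 to 0.266 over all genes with 1 library left out. In the other pairing it was 0.0775, 0.026 over genes of at least 10 CPM, -0.0345 with Spearman in place of Pearson correlation, and -0.00905 to 0.167 with 1 library left out. At an unadjusted p under 0.01 more genes enter, and the ageing calls shared 432 in place of 116. The knockout calls at 2 ages shared 40 genes in place of 1. Of these, 21 were higher at both ages (11.2 by chance, Fisher's exact p = 0.00516). Another 19 were lower at both (5.87 by chance, p = 6.24e-06 in the same exact test). That test treats genes as independent, which they are not.

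No named gene that was called changed sign. Among values never called, Acta1 in young knockout muscle was -0.00233 and turned to 0.00464 with only the groups compared, 0.00731 with protein-coding genes and 0.00277 at 1 CPM. With 1 library left out it ran from -0.089 to 0.1. The other changes of sign came with a library left out. In young knockout they were Heyl (-0.0956 to 0.374), Xist (-6.39 to 3.31) and Ddx3y (-0.636 to 0.436). In old knockout they were Notch3 (-0.327 to 0.295), Heyl (-0.173 to 0.321), Pax7 (-0.264 to 0.552), Xist (-0.463 to 0.646) and Ddx3y (-6.41 to 3.06). With age they were Acta1 in controls (-0.0279 to 0.0819) and Notch2 (-0.0665 to 0.191) and Hey1 (-0.0657 to 0.302) in knockout muscle. Of the named values with a library left out, 797 kept direction and side of the threshold, 307 lost the call, 10 gained one and 38 changed sign. Under the other alternatives these were 849, 71, 2 and 3.

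The planned comparison with no filter is void, since the filter removed no gene, and the pseudocount alternative does not apply to counts. The fit of only the groups compared was not run for the interaction, which uses all groups. Depth limits the 2086 genes (13.7%) with a mean under 0.772 CPM, where counting error exceeds a coefficient of variation of 20.1%, the common value between replicates.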

Other observations

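The values in this part were chosen after the data were seen. In edgeR with age and genotype fitted to the 12 control libraries, 23 genes, Pofut1 set aside, passed between Cre and floxed muscle. Genes of immature fibres were among them and higher in Cre muscle: Myh3 (log2 1.60, adjusted p = 0.0132), Tnnt2 (1.49, adjusted p = 0.000994), Chrng (2.82, adjusted p = 0.0389) and Chrna1 (0.88, adjusted p = 0.0134). Within a single age none of these 4 was called in edgeR. Myh3 was at 22.1 ± 0.984 CPM in young Cre against 5.96 ± 3.5 CPM in young floxed muscle, and at 20.5 ± 4.7 against 8.2 ± 1.34 CPM in old muscle (n = 3 each). All 6 Cre libraries (16.5 to 25.7 CPM) lay above all 6 floxed libraries (3.72 to 10 CPM). Tnnt2, cardiac troponin T, which immature fibres express, was at 5.47 ± 0.915 against 1.58 ± 0.341 CPM in young and 8 ± 1.06 against 3.44 ± 0.317 CPM in old muscle. Among young knockout libraries Myh3 ran from 5.82 to 41.7 CPM. The regeneration list was called upward in young Cre against young floxed muscle with the preset (20 of 22 positive, median 0.48), but not with an estimated correlation (adjusted p = 0.651).

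Fibre type and interferon genes leaned apart between old Cre and old floxed controls, with no member called over all genes. Slow fibre genes were negative in 18 of 19 in old Cre muscle (median -1.15, 2 lower when adjusted over the list alone), and interferon response genes were positive in 23 of 26 (median 0.62, 10 higher when adjusted over the list alone). Neither list was called with an estimated correlation (adjusted p = 0.852 and 0.762). LOC102640133 separated the Cre controls, at 1.71 to 2.69 CPM, from the other 12 libraries, at 10.3 to 17.7 CPM. In Cre against floxed muscle, genes with an unadjusted p under 0.01 crowded most on chromosome 2 from 150 to 160 Mb, where Pofut1 lies, at both ages (0.003 and 0.001 of 1000 shuffles).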
